A study of Mus musculus with 2 samples.

How the data were processed

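Single-cell RNA sequencing was analysed from 2 libraries of mouse endometrial epithelial organoids, 1 from PND3 and 1 from PND15 uteri (C57BL/6J, 10 females pooled per age, 8 days of culture). Per the labels' protocols, organoids were dissociated with trypsin, strained, loaded on a 10x Genomics Chromium instrument with 3' version 3 chemistry for a target of 5000 cells, and sequenced on a NovaSeq instrument. The deposited values are raw UMI counts per gene and barcode, in whole numbers, in matrices already filtered to called cells; per the submitters' processing notes the tools were Cell Ranger 7.2.0 and Seurat 5.1.0 with the GRCm39 genome build. The annotation release used by the authors is not given in the sources used here. The reference at hand was GENCODE vM21 on GRCm38, another build, so no coordinates are printed, and it served only to ask which gene names overlap. Both files listed the same 56941 features; 297 of them share a symbol with another feature, in which case the feature with the most UMIs was used, and 310 have no symbol. Sums of mt-Co2 (3094 UMIs), mt-Co3 (4986) and mt-Atp6 (14515) were far below that of mt-Nd1 (454219), so mitochondrial percentages may be understated.

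Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which removed 266 PND3 and 237 PND15 barcodes. Scrublet, run in scanpy per library with an expected doublet rate of 5%, marked 23 PND3 (0.617%) and 3 PND15 cells (0.109%), which were removed. At such rates the caller has not worked, so doublets largely remain, and an alternative removed the 5% of cells with the highest Scrublet score in each library. The kept cells held 63349637 UMIs at PND3 and 70586618 at PND15, with medians of 4203 and 4929 genes and 2.24% and 1.67% mitochondrial UMIs. A count of 0 in a summed library therefore allows under 1 CPM, and precision of a ratio is set by the UMIs of the rarer side.

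UMI counts were summed over the kept cells of each library and scaled to CPM of the summed total of that library. Each PND15 to PND3 ratio has an exact conditional binomial 95% interval, and shares of cells have exact Clopper-Pearson intervals; both cover counting error only, and for a count of 0 the limit given is 3 counts of the total. With 1 library per age no test was run and no p-value is given. Totals under 3 UMIs were set to 3 before log2 ratios were taken, so that a gene at 0 gives a lower bound. Genes with at least 50 CPM in 1 library entered the counts of genes at ratios of at least 2 or at most 0.5. The genes named in the text follow a fixed rule: the 12 highest and the 12 lowest ratios (1 CPM added for ranking) at 50 CPM or more, without mitochondrial, ribosomal protein, histone, haemoglobin, Xist and Tsix and unnamed predicted genes, plus a fixed panel (Foxa2, Trp63, Krt5, Krt14, Foxj1, Lgr5, Axin2, Sox9, Esr1, Pgr, Pax8, Krt8, Epcam, Cdh1, Vim, Mki67, Ltf, Wnt7a, Aldh1a1 and Ly6a) and up to 4 members of each list with the largest ratios and at least 50 CPM, or 10 CPM where fewer reach it. Prap1, Krt10, Krt17 and the noncoding neighbours of Hox genes were named after their values were seen. Values of some genes that the rule selects are not reported here. Within clusters with 100 cells of each library the rule would have named the 5 highest and 5 lowest genes; no cluster qualified, and the 12 highest and 12 lowest of the non-squamous clusters were named in their place.

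Fixed lists were 23 gene lists (Wnt pathway targets, Notch pathway, YAP and regenerative state, estrogen and progesterone response, Hox genes, Mullerian duct and uterine epithelial transcription factors, simple epithelial keratins, stratified keratins, mucins and antimicrobial secretions, tight junction and adhesion, basement membrane and integrins, mesenchymal transition, S phase, G2 and M phase, immediate early and dissociation stress, interferon response and MHC class I, glycolysis and hypoxia, cholesterol synthesis, unfolded protein response, retinoid metabolism, growth factor ligands of the niche, imprinted and fetal growth genes, mitochondrially encoded mRNAs) and markers of 14 classes. The classes were luminal, glandular, ciliated, basal or stratified squamous, cornified squamous, secretory and stem or progenitor epithelium, stroma or fibroblast, smooth muscle or pericyte, endothelium, immune, mesothelium, erythroid and cycling. A member counted as measured at 10 CPM in 1 library and as higher or lower at a 2-fold ratio whose interval excluded 1. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins, as a description of these libraries.

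Cells were clustered jointly without integration (log of counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). A cluster was named for a class when at least 3 of its markers lay at 2-fold or more over the other cells and at 10 CPM, 1 of them among the 10 leading genes by fold, and when this held in each library with at least 20 cells of the cluster; these cutoffs were set after the data were seen. Shares of cells with a UMI and phase shares used cells thinned to 5500 UMIs, the 10th percentile of the shallower library rounded down, and phases came from scanpy scores of the S phase and G2 and M phase lists with both libraries scored together. The comparison of clusters 4, 5 and 6 with clusters 8, 9 and 12 was added after the clusters were seen.

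Ratio intervals, 2-fold ratios and list percentiles were tested on simulated data made from the summed PND3 counts of all deposited barcodes at the depths of both libraries. Thinning was checked on PND15 cells and share intervals on simulated counts, while phase shares, cluster naming and cluster shares had no simulated check. The ratio interval held the true ratio in 94.8% of 3339 genes, all 40 genes simulated at each of 0.25-, 0.4-, 2.5- and 4-fold passed 2-fold, 0 of 40 at 1.5-fold and 0% of 3139 unchanged genes did, and 5% of unchanged lists, drawn over 240 genes, lay outside the central 95%. These lists were few, so the 5% is a rough value. Both libraries were simulated as independent Poisson counts, so the simulation covers counting error only. It holds no variation between cultures, libraries or cells and no genes that vary together, and says nothing on how far such variation moves a ratio or list. Alternatives covered the cell filters (all barcodes, or 1500 genes and at most 10% mitochondrial UMIs), doublets, scaling, per-cell means, the CPM floor, G1 cells, thinning, phase scoring and clustering settings. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and bedtools 2.31.1.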

Results

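Single-cell transcriptomes were measured in mouse endometrial epithelial organoids, which are hollow epithelial structures grown in gel from the lining of the uterus. One culture had been started from uteri collected on postnatal day (PND) 3 and the other from uteri collected on PND15, each from a pool of 10 C57BL/6J females. Both were dissociated after 8 days of culture. There was 1 library per age and no replicate, so age of the donor and culture could not be separated. The PND3 library held 3994 barcodes and 64318599 unique molecular identifiers (UMIs), against 3000 barcodes and 70919193 UMIs in the PND15 library, where 5000 cells per library had been targeted. After filtering, 3705 PND3 cells with a median of 15375 UMIs and 2760 PND15 cells with a median of 20686.5 UMIs were kept. Levels are summed UMIs of a library scaled to a common total (CPM). Intervals are exact 95% intervals that cover counting error only, and no ratio was tested.

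The first comparison asked how gene expression in the organoid epithelium differed with the age of the uterus it came from. Genes of stratified squamous epithelium were lower in PND15 organoids, to the point of being nearly uncounted for some but not for all. Krt5 (ENSMUSG00000061527) and Krt14 (ENSMUSG00000045545), the keratin pair of basal stratified cells, stood at 1068 and 1154 CPM at PND3 and at 0.198 and 0.142 CPM at PND15, which is 5383-fold (95% interval 3208 to 9846) and 8149-fold (4431 to 16994) lower. Trp63 (ENSMUSG00000022510), a transcription factor of basal cells, was 34.1-fold lower (27.9 to 42.2), with 3003 UMIs at PND3 and 98 at PND15. The keratins Krt10 and Krt17, picked after their values were seen, still gave 1062 and 8764 UMIs at PND15, against 71281 and 88598 at PND3. In the other direction, Klk1 (ENSMUSG00000063903), a tissue kallikrein protease, was 114-fold higher at PND15 (108 to 119.8, 25.1 to 2863 CPM). Car4 (ENSMUSG00000000805), a membrane carbonic anhydrase, was 90.5-fold higher (82.4 to 99.6). Of 3764 genes at 50 CPM or more in at least 1 library, 323 had a PND15 to PND3 ratio of at least 2 and 367 a ratio of at most 0.5.

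The 12 genes with the lowest ratios were Cstdc5, Krtdap, Lgals7, Krt14, Krt5, Krt16, Krt6a, Stfa3, Ly6d, Calm4, Ndufa4l2 and S100a9, most of them genes of keratinocytes. Cstdc5, a cystatin family gene, was counted at 3259.7 CPM at PND3 and at 0 UMIs at PND15, which is at least 76696-fold lower against a floor of 3 UMIs over the group. Stfa3, a stefin of the same inhibitor family, was likewise at 0 UMIs at PND15 and at least 10262-fold lower. Krtdap, a protein of differentiating keratinocytes, gave 143340 UMIs at PND3 and 2 at PND15, a ratio of 79858 with an interval from 22106 to 659415. Krt16 and Krt6a were 1835-fold and 7072-fold lower, Ly6d 616-fold, S100a9 1245-fold and Ndufa4l2 422-fold lower. Reads shared by closely similar genes may be lost or assigned to another member of the family. Such families are the stefin and cystatin cluster, the Krt6 genes, the keratins related to Krt16 and the Klk1 family. The level of a single member of these families is therefore uncertain.

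The 12 genes with the highest ratios were Klk1, Car4, Kap, Hsd11b1, Klk1b24, Abcb1b, Aqp8, Klk1b21, Cyp26a1, Akr1c18, L3mbtl4 and Dcdc2a. Hsd11b1, which regenerates active glucocorticoid, stood at 16.2 CPM at PND3 and 738 at PND15, 45.7-fold higher (42.9 to 48.6). Abcb1b, a drug efflux pump, was 39.9-fold higher (38.0 to 42.0), and Kap, a kidney androgen-regulated protein, was 66.7-fold higher. Cyp26a1, which degrades retinoic acid, was 47.3-fold higher (37.8 to 60.0) and Akr1c18, which inactivates progesterone, 41.2-fold higher. The water channel Aqp8 was 36.1-fold higher, Klk1b24 114-fold, Klk1b21 40.1-fold, L3mbtl4 39.5-fold and Dcdc2a 30.5-fold higher. Prap1, a proline-rich secreted protein singled out after its values were seen because it led both libraries, stood at 14336 CPM at PND3 and 72001 at PND15.

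**Figure D1:**
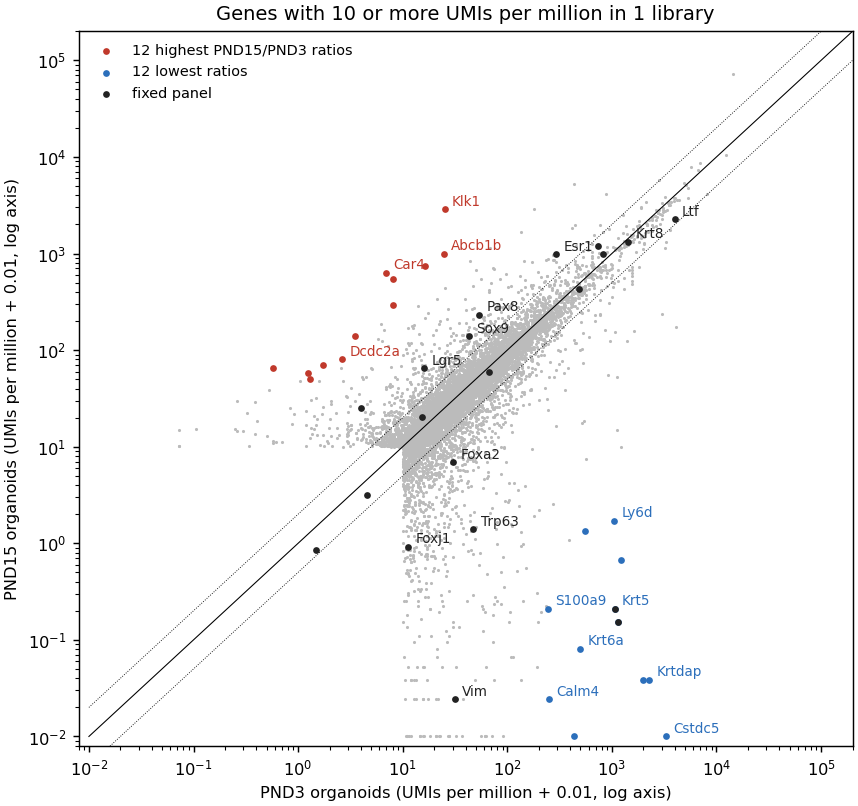
Each point is 1 gene with 10 CPM or more in 1 library, with its PND3 level on the x axis and its PND15 level on the y axis (CPM plus 0.01, both log axes). The solid line marks equal levels and the dotted lines a 2-fold difference; coloured points are the 12 highest and 12 lowest ratios and black points the fixed panel, with Krt5 at 1068 and 0.198 and Klk1 at 25.1 and 2863 CPM.

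Gene lists, filters, thresholds and comparisons were set before the data were examined unless stated otherwise. Stratified keratins had the lowest median log2 ratio of the 23 lists, -8.63, with 11 of 12 measured members lower and a percentile of 0 among 10000 random lists matched on expression. All 10 basal or stratified squamous markers (median -8.74, percentile 0) and all 9 measured cornified markers (-6.22, percentile 0) were lower at PND15. Among them were Dsc3, a desmosomal cadherin, at 74.7 CPM against 2 UMIs (ratio 2636, interval 729 to 21770.4) and Krt1 at 123 against 0.510 CPM. Ciliated markers were lower in 6 of 6 measured members (median -4.31, percentile 0.010). Foxj1, the transcription factor of motile cilia, stood at 11.3 against 0.907 CPM and Dynlrb2 at 32.3 against 0.0425 CPM. Glandular markers were lower in 3 of 5 (median -2.15, percentile 0.070). Foxa2, the forkhead factor of uterine glands, was 4.43-fold lower (4.01 to 4.91) and Cxcl15, a glandular chemokine, 54.0-fold lower, while Cxcl17 stood at 346 and 291 CPM. Luminal markers had 1 of 7 higher and 2 lower (median 0.32, percentile 94.2), with Calb1 2.17-fold higher. Simple epithelial keratins lay in the middle (median -0.12, percentile 43.7, 1 of 5 lower). Krt8, Epcam and Cdh1 were within 1.5-fold between the whole libraries, at 1434 and 1323, 822 and 984, and 488 and 427 CPM. With squamous-like and ciliated-like clusters set aside, as described below, Krt8 was 1.57-fold and Cdh1 1.25-fold lower at PND15. Epcam stood there at 995 and 983 CPM, and Calb1 was 1.42-fold higher at PND15.

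Stem or progenitor markers were higher as a group at PND15 (median 0.79, percentile 99.95), with 3 of 8 higher and 1 lower. Lgr5, a Wnt-target receptor, was 4.03-fold higher (3.76 to 4.32), Sox9 3.24-fold and Aldh1a1, a retinal dehydrogenase, 6.36-fold higher. The hyaluronan receptor Cd44 was lower (96.8 to 6.91 CPM) and Ly6a stood at 732 and 1183 CPM. Of Wnt pathway targets, 1 of 9 was higher and 3 lower (median -0.01, percentile 74.0), and Axin2, a feedback inhibitor of Wnt signalling, gave 285 UMIs at PND3 and 220 at PND15. Notch pathway genes were lower in 3 of 6 (median -1.63, percentile 0.210), led by the target Nrarp at 71.1 against 2.31 CPM and the receptor Notch1 at 95.8 against 18.1 CPM. In the PND3 squamous-like clusters described below, Nrarp and Notch1 stood at 172 and 224 CPM. With squamous-like and ciliated-like clusters set aside, 3 of 5 measured members were lower, Notch2 at 2.08-fold. Hes1 stood there at 383 and 473 CPM and Jag1 at 53.5 and 62.8 CPM. Mullerian duct and uterine epithelial transcription factors had a median of -0.40 (percentile 1.43) with 1 of 17 higher, Pax8 at 4.27-fold (4.11 to 4.43), and 3 lower; with per-cell means the percentile was 6.34. Only 3 of 16 listed Hox genes were measured, Hoxb6, Hoxb7 and Hoxb8 (median 0.98, percentile 98.4, none called), and 12 had no UMI in either library. Estrogen and progesterone response genes went both ways (3 of 11 higher, 3 lower, median -0.12, percentile 48.7). The estrogen receptor Esr1 was 3.35-fold higher (3.30 to 3.40) and complement C3 4.61-fold higher, while Wnt4 was 3.62-fold lower. The progesterone receptor Pgr stood at 15.3 and 20.4, Wnt7a at 1.48 and 0.850 and lactoferrin, Ltf, at 3972 and 2253 CPM.

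Glycolysis and hypoxia genes were lower in 15 of 17 measured members at PND15 (median log2 ratio -1.67, percentile 0). These included Egln3, an oxygen-sensing prolyl hydroxylase, at 9.16-fold (8.80 to 9.54), Bnip3 at 5.40-fold, Pdk1 at 4.42-fold and Ndrg1 at 4.39-fold lower. Interferon response and MHC class I genes were lower in 9 of 15 (median -1.40, percentile 0), with Ifit1 13.3-fold and the ubiquitin-like Isg15 9.36-fold lower. Cholesterol synthesis genes had a median of -1.01 (percentile 0) with 8 of 16 lower, such as Msmo1 at 2.39-fold and Idi1 at 2.36-fold. Mucins and antimicrobial secretions had a median of -0.88 (percentile 0.020), with 6 of 13 lower and 2 higher. S100a8 was 1914-fold, the lectin Reg3g 571-fold and the protease inhibitor Slpi 12.7-fold lower. Secretory epithelial markers had 2 of 9 higher and 2 lower (median -0.67, percentile 0.590), with Lcn2, a siderophore-binding lipocalin, 2.03-fold higher and Muc1 at 119 and 64.6 CPM. Mesenchymal transition genes were lower in 3 of 4 measured (median -1.72 with Vim at its bound, percentile 0.390). Vim itself, the intermediate filament vimentin, gave 1981 UMIs at PND3 and 1 at PND15, a ratio of 2207 with an interval from 396 to 87227. Postn, the 1 stromal marker measured, moved the same way (95.4 and 2.71 CPM). Basement membrane and integrin genes were higher as a group (median 0.56, percentile 99.97), although only 3 of 14 passed 2-fold. Members 2-fold or more lower were Col17a1 at 280.4-fold and Itgb4 at 2.54-fold. Tight junction and adhesion genes had 1 of 16 higher, the claudin Cldn10 at 2.47-fold, and 5 lower, including the desmosomal genes Pkp1 at 739-fold and Dsp at 5.88-fold (median -0.15, percentile 30.5). With squamous-like and ciliated-like clusters set aside, 0 of 15 were called higher and 2 lower (median -0.34, percentile 3.7). Cldn10 was 1.63-fold higher there and Dsp 2.56-fold lower.

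G2 and M phase genes were lower as a group at PND15. In cells called G1 the median was -0.05 (percentile 62.1), but this follows by construction. Such cells are called by low scores on this same list and the S phase list. S phase genes were slightly higher, inside the central 95% of random lists with a floor of 20 CPM (percentile 95.04). No member of the S phase list (24 measured, median 0.14, percentile 98.0), the G2 and M phase list (28 measured, median -0.58, percentile 0) or the cycling markers (10 measured, median -0.61, percentile 0.150) passed 2-fold, and Mki67 stood at 67.4 and 59.8 CPM. Stress-related lists did not stand apart. Immediate early and dissociation stress genes had a median of 0.08 (percentile 91.6, 2 of 18 lower, Hspa1a at 4.46-fold and Hspa1b at 2.79-fold), and unfolded protein response genes a median of -0.18 (percentile 26.9, none of 13 called). Mitochondrially encoded mRNAs had a median of -0.29 (percentile 10.0) with 1 of 11 lower. In all, 13 of 23 lists lay outside the central 95% of their random lists.

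These differences compare 2 libraries and have no replicate check, so no test or p-value is given. With a floor of 20 CPM the number of genes at least 2-fold lower was 738, and without a floor 1963 genes were higher and 6939 lower, so that the higher genes went from 46.8% to 22.1% of these genes. Scaling to the median of gene ratios moved the median log2 ratio over all genes from -0.10 to 0.02 and the median of Wnt pathway targets from -0.01 to 0.09, with no other of the 23 lists changing side.

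A second comparison asked which cell classes each culture held. Clustering of both libraries together gave 12 clusters, 11 of which drew over 95% of their cells from 1 library, so a cluster here may reflect its library as much as a cell type. Squamous-like cells made up 37.5% of the PND3 library (1389 of 3705 cells, exact binomial interval 35.9 to 39.1%) and 0 of 2760 PND15 cells, which allows a share of up to 0.109% by the limit of 3 counts and 0.134% by the exact interval. They formed a cornified-like cluster 2 (497 cells), a basal-like cluster 3 (705 cells) and a basal-like cluster 10 (187 cells) that also carried the cycling markers. A ciliated-like cluster 11 held 95 PND3 cells (2.56%, 2.08 to 3.13%) and 0 PND15 cells. The remaining PND3 cells lay mainly in cluster 4 (unnamed, 856 cells), the secretory-like cluster 5 (814 cells) and the cycling cluster 6 (334 cells), and the PND15 cells in cluster 8 (unnamed, 689 cells), cluster 9 (unnamed, 1635 cells) and the cycling cluster 12 (377 cells).

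The cutoffs for naming a cluster were chosen after the data were seen. They kept cluster 4, which had 4 glandular markers raised, Foxa2 and Cxcl15 among them, but none among its 10 leading genes, out of the glandular class. That cluster held 23.1% of PND3 and 0% of PND15 cells. They also left unnamed cluster 1 (2.62% of PND3 and 1.78% of PND15 cells), in which 7 cornified markers were raised but did not meet the cutoffs in its 49 PND15 cells taken alone, and cluster 7, of shallow cells (3.13% and 0.181%). Sizes of clusters other than the squamous-like and ciliated-like classes are given but not read as differences between libraries. Apart from cluster 1, each drew over 95% of its cells from 1 library. Whether its defining genes were the same in the other library could therefore not be measured. No cluster held 100 cells of each library in any of 6 clustering settings, so the planned ratios within clusters gave no value.

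**Figure D2:**
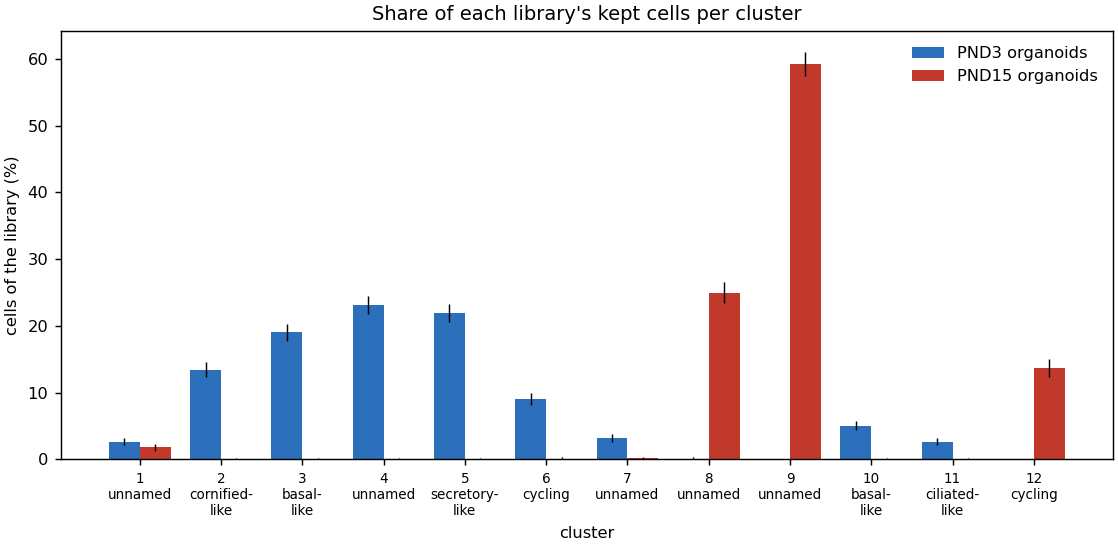
Bars give the share of each library's kept cells (y axis, %) in each of 12 clusters (x axis, with the class name where one was given) for PND3 (blue) and PND15 (red) organoids, with exact binomial 95% intervals as lines. Clusters 2, 3, 10 and 11, squamous-like and ciliated-like, held PND3 cells alone, and cluster 9 held 59.2% of PND15 cells.

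The share of cells with a UMI of Trp63, Krt5 or Krt14, all genes of basal stratified cells, was compared after thinning each cell to 5500 UMIs, which left out 363 PND3 and 220 PND15 cells. It was 52.7% at PND3 (1761 of 3342 cells, 51.0 to 54.4%) and 0.787% at PND15 (20 of 2540 cells, 0.482 to 1.21%), against 74.1% and 3.73% without thinning. Within PND3 the share was 96.0% in squamous-like clusters (median 13030 UMIs per cell) and 24.2% in clusters 4, 5 and 6 (median 17843 UMIs), where Krt5, Krt14, Krtdap and Trp63 ran at 1.55%, 0.830%, 0.923% and 1.34% of their squamous level. Trp63 behaved unlike the keratins: in PND15 clusters 8, 9 and 12 it stood at 0.935% of that level, where Krt5 and Krt14 stood at 0.00628% and 0.00405%, and 18 of the 20 PND15 cells had a Trp63 UMI. In UMIs, Trp63 gave 78 (1.94 CPM) in clusters 4, 5 and 6 and 95 (1.35 CPM) in clusters 8, 9 and 12. In PND3 clusters 4, 5 and 6, Cstdc5, Lgals7, Krt6a, Krt10 and Calm4 also ran at 0.851 to 1.39% of their squamous level, while Ly6d ran at 4.01%. Free RNA in droplets or remaining doublets would give a similar percentage for many squamous genes. Neither was separated from the cells' own RNA here. The share in clusters 4, 5 and 6 is therefore not read as expression, and how much of it is background was not measured.

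Foxa2 UMIs were found in 13.0% of thinned PND3 cells (11.9 to 14.2%) and 3.58% of PND15 cells (2.89 to 4.38%), or 28.8% and 11.9% without thinning. In clusters 4, 5 and 6 at PND3 the share was 17.5%, and in squamous-like clusters, where Foxa2 reached 35.1% of the level of clusters 4, 5 and 6, it was 6.88%. No PND15 cluster that should lack Foxa2 was at hand, so the PND15 share may hold free RNA and is not read as a Foxa2-expressing subset. Esr1 UMIs were found in 42.0% of PND3 and 96.1% of PND15 cells (4.19% in squamous-like clusters), and Lgr5 UMIs in 6.04% (5.26 to 6.91%) and 17.8% (16.3 to 19.3%), against 2.13% in squamous-like clusters. Foxj1 UMIs were found in 2.21% and 0.315%, and in 0.983% of cells of PND3 clusters 4, 5 and 6.

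The combined share of cells in S or G2M phase had overlapping intervals in the cultures, while the phases taken singly did not and ran opposite ways. Cells scored in S or G2M phase made up 22.8% of thinned PND3 cells (21.4 to 24.2%) and 21.1% of PND15 cells (19.5 to 22.7%), and UMIs of Mki67 or Top2a were found in 23.0% and 20.7%. S phase cells were fewer at PND3 (7.81%, 261 of 3342 cells, 6.92 to 8.77%) than at PND15 (10.1%, 257 of 2540 cells, 8.97 to 11.4%). G2M cells were more at PND3 (500 cells, 13.8 to 16.2%) than at PND15 (279 cells, 9.79 to 12.3%), and free RNA, which enters phase scores, was not separated from either. Within PND3, the cornified-like cluster 2 had 0.648% of cells in these phases, the basal-like cluster 3 had 24.4% and the basal-like cluster 10 had 100%. When each library was scored on its own the shares were 23.7% at PND3 and 29.1% at PND15, so the order of the libraries depends on the scoring.

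One further comparison, added after the clusters were seen, asked what differed once squamous-like and ciliated-like clusters were set aside, with clusters 1 and 7, those of lowest median UMIs per cell (5297 and 1987). It set 2004 PND3 cells of clusters 4, 5 and 6 against 2701 PND15 cells of clusters 8, 9 and 12, and a Krt8 UMI was found in 99.8% and 97.9% of these cells after thinning. Transporters, kallikreins and enzymes of steroid and retinoid metabolism were among the 12 highest at PND15. Abcb1b was 122-fold higher (109.6 to 137), Klk1 74.2-fold (70.6 to 78.0), Car4 58.9-fold, Kap 43.0-fold, Hsd11b1 30.1-fold and Cyp26a1 30.8-fold higher. Klk1b24, Akr1c18, Dcdc2a, Klk1b21, Aqp8 and Tgfb2 completed the 12 highest, the last at 22.9-fold. Antimicrobial, secreted and membrane proteins were among the 12 lowest. Reg3g, an antimicrobial lectin, was 945-fold lower (541 to 1829.7), Sprr2d 365-fold, Mgat4c 263-fold, Lgi2 356-fold and Itln1 221-fold lower. Igfbp5, an insulin-like growth factor binding protein, was 214-fold, the water channel Aqp4 131-fold, Lypd2 108-fold and Cxcl15 89.2-fold lower. Cstdc5, Krtdap and Ly6d, also among the 12 lowest here, reached 1.01%, 0.923% and 4.01% of their squamous-like level in these PND3 cells, and free RNA or doublets were not separated from these. Several of these genes also lead clusters 4 or 9, each drawn from 1 library, so their ratios and the clustering rest on the same values.

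Esr1 stayed higher at PND15 at 2.23-fold (2.20 to 2.27), as did Pax8 at 3.56-fold, Lgr5 at 2.89-fold, Ly6a at 2.79-fold, Sox9 at 2.67-fold, Aldh1a1 at 4.30-fold and C3 at 3.08-fold. The gland factor Foxa2 was 5.78-fold lower (5.21 to 6.42), Ltf 2.67-fold, Slpi 11.4-fold and Muc1 2.76-fold lower. Mucins and antimicrobial secretions were lower in 7 of 11 measured members with none higher (median log2 ratio -1.42, percentile 0), interferon response and MHC class I genes in 10 of 16 (-1.78, percentile 0). Glycolysis and hypoxia genes were lower in 13 of 16 (-1.26, percentile 0), where Egln3 was 7.32-fold and Bnip3 4.67-fold lower. Cholesterol synthesis genes were lower in 3 of 16 (-0.74, percentile 0). Basement membrane and integrin genes were higher in 5 of 13 with none lower (0.67, percentile 99.99), including Lama3 at 3.32-fold. Retinoid metabolism genes, at a median of -0.44 in the whole library (percentile 5.69, 4 of 9 higher and 4 lower), were higher here as a group (median 0.56, percentile 99.6, 4 of 8 higher and 2 lower). Cyp26a1 stood at 1.89 against 58.4 CPM and Aldh1a2, which makes retinoic acid, was 8.94-fold higher (7.84 to 10.2). The median of the Mullerian and uterine transcription factors was -0.04 here (percentile 70.2), that of the Notch pathway -1.01 (percentile 0.540) and that of the stratified keratins -6.04 (percentile 0), where Krt5, Krt14, Krt6a and Krt10 stood in these PND3 cells at 0.830 to 1.55% of their squamous-like level and Krt13 and Krt15 at 3.36% and 3.47%.

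Of genes at 50 CPM or more, 277 had a ratio of at least 2 in these clusters and 314 a ratio of at most 0.5; 255 of the 323 higher and 208 of the 367 lower genes of the whole library were among them. This comparison also has no replicate and no test, and the choice of clusters rests on the same data.

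**Figure D3:**
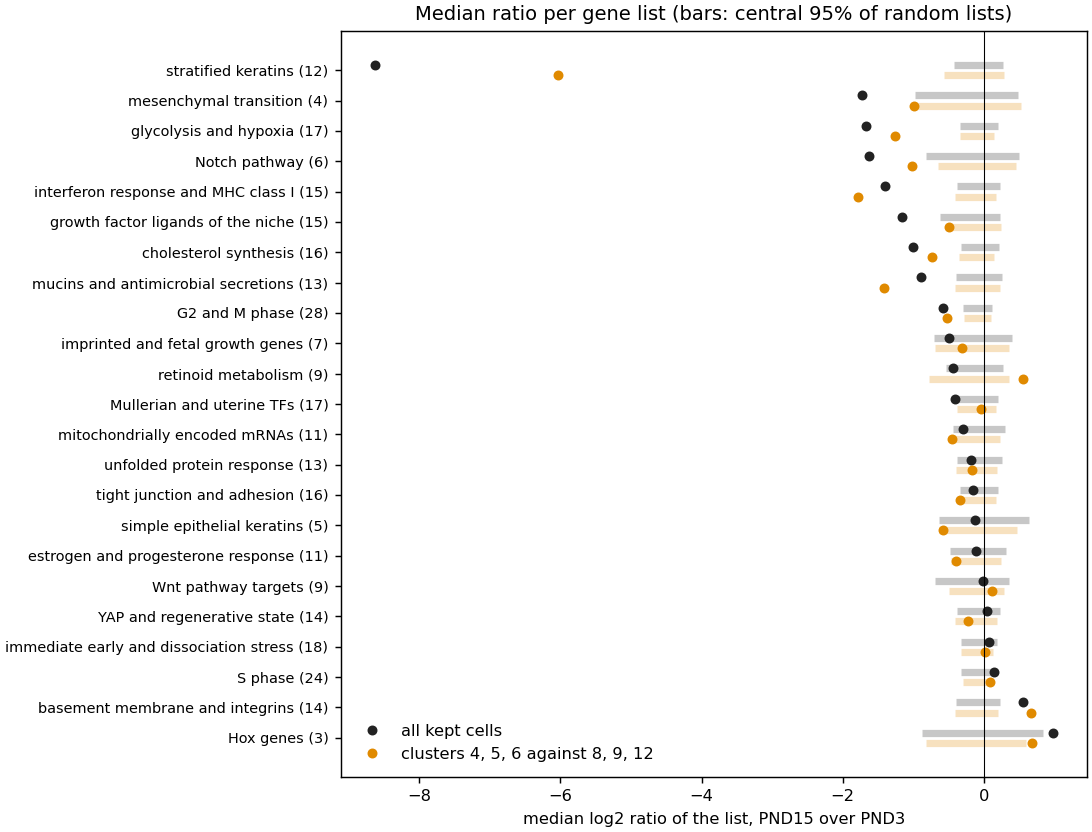
Points give the median log2 ratio of PND15 over PND3 (x axis) of each fixed gene list, with the number of measured genes in the whole library in brackets, for all kept cells (black) and for clusters 4, 5 and 6 against clusters 8, 9 and 12 (orange). Pale bars span the central 95% of 10000 random lists matched on expression; the stratified keratins lie lowest at -8.63 and the basement membrane and integrin list lies above its bar in both, at 0.56 and 0.67.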

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

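The 3 tests of explanations in this part were chosen only after the keratin difference had been seen. The barcodes left out by the cell filters entered no comparison of the report, only the alternative that used all barcodes. In the 266 PND3 barcodes left out, Trp63, Krt5 and Krt14 gave 193 of 301307 UMIs, or 641 CPM, above the 9.96 CPM that a count of 0 allows. Any count over 3 UMIs passes that limit, so it shows only that these genes were counted. Their level was lower than in the kept PND3 cells, where Krt5 alone stood at 1068 and Krt14 alone at 1154 CPM. The 237 PND15 barcodes left out gave 2 of 205791 UMIs of these genes, or 9.72 CPM, below their limit of 14.6 CPM. Median mitochondrial shares of these barcodes were 36.4% at PND3 and 57.1% at PND15.

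Krt5 and Krt14 were abundant in the PND3 library and nearly uncounted in the PND15 library. Trp63 (98 UMIs), Krt10 (1062) and Krt17 (8764) were lower over the whole PND15 library but still counted. Krt17 stood at 147, 204 and 122 CPM in clusters 4, 5 and 6, and at 183, 102 and 132 CPM in clusters 8, 9 and 12. Krt10 stood at 45.4 CPM in the former clusters together and at 15.0 CPM in the latter. Depth as the cause of the low Krt5 and Krt14 counts at PND15 is argued against. PND15 was the deeper library, and at equal depth 0.787% of its cells had a UMI of Trp63, Krt5 or Krt14 against 52.7% at PND3. PND3 squamous cells from a tissue outside the Mullerian tract are also argued against: 6 of 6 Mullerian genes (Pax8, Pax2, Emx2, Sox17 and Foxa2 among them, a list written after the clusters were seen) stood in the squamous-like clusters at 23.1 to 65.7% of their level in clusters 4, 5 and 6, each over 5 times the free-RNA ratio of at most 0.944% set by Prap1. Whether PND3 squamous cells were carried over from the cervix or vagina or arose from uterine epithelium cannot be told apart, because Hoxa10, Hoxa11 and Hoxa13, which would separate these regions, gave 0 UMIs in the squamous-like clusters and none elsewhere in either library. An age-dependent capacity for squamous differentiation in culture is a hypothesis that stays open, untested with 1 library per age.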

How the results depend on the processing

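Settings chosen only after the data were seen were clusters 4, 5, 6, 8, 9 and 12 alone, leaving out clusters 1 and 7, removing the 5% highest Scrublet scores, a total without Prap1, and thinning to 2000 UMIs. The numbers of genes at least 2-fold higher and lower stayed within 1.5 times their values of 323 and 367 under every setting except the floor: 738 genes were lower with a floor of 20 CPM, and 1963 were higher and 6939 lower with no floor beyond 3 UMIs, where 27439 genes entered in place of 3764; why the excess was on the lower side was not tested. Scaling to the median of gene ratios gave 382 and 324, and a total without Prap1 376 and 337. Between 11 and 14 of 23 lists lay outside the central 95% of random lists, and 36.2 to 38.6% of PND3 cells were squamous-like. Shares of cells with a UMI moved with depth by construction. For Trp63, Krt5 or Krt14, the PND3 share was 74.1% without thinning, 39.3% with 2 UMIs or more and 43.6% thinned to 2000 UMIs, and the PND15 share 3.73%, 0% and 0.220%. For Foxa2, PND3 gave 28.8% without thinning, 2.09% with 2 UMIs or more, 4.93% thinned to 2000 UMIs and 17.5% in clusters 4, 5 and 6, and PND15 gave 11.9%, 0.433% and 1.21% under the first 3 of these. The order of the libraries held throughout for both measures. The share in S or G2M phase was 20.6% at PND3 in clusters 4, 5 and 6, and at PND15 23.3% without thinning, 24.0% with the stricter cell filter and 29.1% with each library scored separately; the last put PND15 above PND3 (23.7%), as did, by little, the stricter filter (23.8% at PND3) and clusters 8, 9 and 12 against 4, 5 and 6 (20.7% at PND15). The cause of these shifts was not tested. Of the median ratios of single lists, 190 values under planned and 78 under added settings stayed close to their starting value, and 17 and 14 moved, most with the floor or with clusters 4, 5, 6, 8, 9 and 12 alone. Medians that changed side were those of retinoid metabolism (-0.44, to 1.12 at a floor of 20 CPM, 0.56 in those clusters and, the other way, -2.05 without a floor), estrogen and progesterone response (-0.12, to 0.15 at a floor of 20 CPM and 0.42 without a floor), Wnt pathway targets (-0.01, between -0.53 without a floor and 0.21 at a floor of 20 CPM, and 0.19 with per-cell means), YAP and regenerative state (0.05, to -0.02 in G1 cells and -0.22 in those clusters), immediate early genes (0.08, to -0.04 with per-cell means) and simple epithelial keratins (-0.12, to 0.07 with per-cell means). Lists that came inside the central 95% were S phase (percentile 95.04 at a floor of 20 CPM, 94.1 in those clusters, 97.1 without clusters 1 and 7, 97.4 without Prap1), G2 and M phase (62.1 in G1 cells, by construction), growth factor ligands (11.5 at a floor of 20 CPM, 2.62 in those clusters) and the Mullerian transcription factors (6.34 with per-cell means, 3.61 without a floor, 3.23 in G1 cells, 70.2 in those clusters). Lists that came outside it were retinoid metabolism under the first 3 settings named for it, estrogen and progesterone response without a floor (99.5) and mitochondrially encoded mRNAs in those clusters (1.54). No paired analysis was possible, because each age had 1 library from its own pool of females, and no result comes from a test. Ratios within clusters could not be had under any clustering setting, since no cluster held 100 cells of each library. Depth limits statements on genes under a few CPM, such as Axin2 and Wnt7a, and the Foxa2 share at PND15.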

Other observations

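The 3 tests on the glycolysis and hypoxia genes were chosen only after the result was seen, and the test on the Hox genes before it. Growth factor ligands of the niche were lower in 8 of 15 measured members at PND15, with 1 higher (median log2 ratio -1.15, percentile 0.130, 1 member at its bound), but with a floor of 20 CPM the median was -0.33 at percentile 11.5, inside the central 95% of random lists. The exception was Tgfb2, a transforming growth factor, at 24.1-fold higher (21.8 to 26.6), while Wnt4 was 3.62-fold lower and the epidermal growth factor receptor ligand Hbegf stood at 558 and 617 CPM. In clusters 4, 5 and 6 against 8, 9 and 12 the median was -0.49 (percentile 2.62), also inside it. YAP and regenerative state genes went both ways (2 of 14 higher, 3 lower, median 0.05, percentile 84.8): Ccn2, a matricellular YAP target, was 4.71-fold higher (4.45 to 4.99). Imprinted and fetal growth genes had a median of -0.49 (percentile 7.65, 1 of 7 higher, 2 lower), with the chromatin protein Hmga2 2.33-fold higher.

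Markers of non-epithelial cells were mostly unmeasured. Of stroma or fibroblast markers only Postn, a matricellular protein, reached 10 CPM, at 95.4 CPM at PND3 and 2.71 at PND15, and it stood at 139.9 and 2.72 CPM in clusters 4, 5 and 6 against 8, 9 and 12. Smooth muscle or pericyte markers gave Notch3 at 42.5 and 4.39 and Acta2 at 32.8 and 26.9 CPM, and endothelium markers gave Pecam1 at 59.6 and 4.59 and Egfl7 at 18.7 and 15.6 CPM. Among immune markers Cd68 stood at 56.7 and 79.7 CPM, and Ptprc, the leukocyte phosphatase CD45, was 76.7-fold higher at PND15 (51.4 to 119.9, 0.379 to 29.0 CPM) with no other immune marker but Cd68 measured. No cluster was named immune, and 2043 of the 2050 PND15 UMIs of Ptprc lay in clusters 8, 9 and 12. In clusters 4, 5 and 6 against 8, 9 and 12, Ptprc stood at 0.573 and 29.1 CPM and Pecam1 at 77.7 and 4.61 CPM. No mesothelium or erythroid marker reached 10 CPM.

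Hox genes were counted almost only from the Hoxb group in both libraries: 10 Hoxb genes gave 48609 UMIs, against 11 UMIs over 11 Hoxa genes, 1 over 9 Hoxc genes and 0 over 9 Hoxd genes. Reads lost where annotated genes overlap on the same strand stay open as a cause: in GENCODE vM21 the median share of exon bases so covered was 0% in the 30 Hox genes under 20 UMIs and also 0% in the 8 with 500 UMIs or more, with 4 of the 30 covered over more than 10%. The prediction written beforehand took values this low as excluding it, which was wrong by design, because that annotation is on GRCm38 and the counts are on GRCm39, whose gene models were not tested. Of noncoding neighbours, Hotair, Haglr and Hoxa11os gave 0 UMIs, Hoxd3os1 gave 1, Hotairm1 in the Hoxa group 181, Hoxb3os 504 and Hoxb5os 947. No biological explanation was tested, because both ages showed the pattern.

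Glycolysis and hypoxia genes were lower at PND15 in 15 of 17 measured members, with a median log2 ratio of -1.67. The squamous-like cells of the PND3 library alone are argued against as the cause, since the median was -1.26 in clusters 4, 5 and 6 against 8, 9 and 12. The larger part of PND15 counts taken by Prap1 is argued against too, since leaving it out of the total moves every gene alike and brought the median only to -1.58. More low-quality cells in 1 library stay open: without clusters 1 and 7, those of lowest median UMIs, the median was -1.66, but leaving them out moved next to nothing (322 and 366 genes at 2-fold against 323 and 367), so this test decides nothing, and cluster 1 was not shown to be of low quality. Oxygen supply or organoid size at harvest and the age of the uterus may each lie behind the difference, and with 1 culture per age these stay open and untested.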
